A study of Sus scrofa with 4 samples.

How the data were processed

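Single-cell RNA of pig embryos and endometrium, at 9 and 12 days of pregnancy, was measured in 4 libraries, 1 per group. Cells were prepared by enzymatic dissociation, papain and dispase for embryos and collagenase with dispase for endometrium, and libraries with a 3' droplet kit, per the labels' protocols. The deposited values are counts of UMIs per gene and barcode, made with Cell Ranger 6.1.2 on Sscrofa11.1, per the submitters' processing notes. The header of the day 9 embryo names Cell Ranger 4, and the headers of the other 3 libraries 6.1.2, per the file headers. How the submitters chose cells is not given in the sources used here. The day 9 embryo holds 657829 deposited barcodes, 92991 of them with no UMI, and the other 3 libraries hold 8105 (day 12 embryo), 9483 (day 9 endometrium) and 11757 (day 12 endometrium), each with 500 UMIs or more. Of the barcodes of those 3 libraries, 89.3%, 99.9% and 99.9% stand among the barcodes of the day 9 embryo. A shared barcode list alone does not account for the higher shares of both endometrial libraries, and whether RNA passed between libraries in sequencing stays open; which libraries were sequenced together is not given in the sources used here. Of 21280 genes, 14811 carry a symbol in the files, and 694 more symbols came from a reference table; symbols are used as given and no coordinates were used.

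Cells of the day 9 embryo were called at 0.1 of the 99th percentile of the top 3000 totals, 2759.47 UMIs, which gave 7011 barcodes. Cells needed 1000 UMIs, 500 genes and at most 20% mitochondrial UMIs (13 genes), which left 7001, 6764, 7984 and 8962 in the day 9 embryo, day 12 embryo, day 9 endometrium and day 12 endometrium. Scrublet's method, as run in scanpy 1.11.5, marked 1, 107, 0 and 0 doublets, which were removed; under 0.5% were marked in 3 of the 4 libraries, so the doublet caller did not work there. Kept cells held 82526421, 64117722, 26070993 and 25457541 UMIs, with medians of 2784, 2314.5, 1243 and 1067 genes per cell. Each library was clustered alone (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 0.6, seed 0). Clusters were named from 181 matched marker genes of 205 listed: a marker was high at 0.5 or more of its highest cluster level, and a class needed 3 high markers. Such a class was ranked first if the 50 leading genes by fold held 3 or more of its markers, and more than of any other class. Otherwise classes were ranked by the number of high markers times their share of the detected markers. A cluster stayed unnamed when another, unrelated class had 0.5 or more of its markers high, when its 10 leading genes held more markers of an unrelated class than of its own, or on a tie. It also did so when 3 times its median UMIs lay under the median of the library, with no own marker among the leading genes. Related classes, such as stromal and smooth muscle or pericyte, were not set against each other, so clusters with high markers of both were named.

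Counts of a class were summed within a library and scaled to CPM, computed here from the deposited counts. Days were compared within each class that had 50 cells or more on both days, by log2 ratio with 1 CPM added. With 1 library per group no test was run; intervals at 95% are exact binomial for shares and for ratios of levels, exact Poisson for levels, and for differences of shares the root of the summed squares of the exact limits. A ratio against 0 counts is given as a lower bound with 3 counts in place of 0. Genes named in the report follow a rule set before the data were examined: the 10 highest and 10 lowest ratios in the largest class of each tissue and 5 and 5 in the others, at 50 CPM or more on a day, without mitochondrial, ribosomal protein or haemoglobin genes. The rule also names 1 gene in epithelial-like cells that is not reported here. The classes, filters and first set of alternatives were also chosen before the data were examined. The 22 functional gene lists (344 of 386 genes matched) were described by the median log2 ratio of members at 5 CPM or more, and by its percentile among 10000 random lists matched on expression in 20 bins. List members named in the text are up to 4 per list, at 20 CPM or more. Ligand and receptor pairs were compared by their highest class level.

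The ratio step was tested on simulated data with 50 genes at each fold of 4, 2, 0.5 and 0.25. Counts of both days were drawn from a Poisson around a shared mean per gene, changed only by the fold. No spread between cells, animals or libraries was simulated, so the outcomes check the computation and not the comparison of days. In hypoblast-like, trophectoderm-like, stromal-like and epithelial-like cells, 100% of the intervals lay on the simulated side of 1 at every fold. At fold 4 the interval held the simulated value for 94%, 96%, 96% and 96% of genes in those 4 classes, at fold 2 for 94%, 98%, 94% and 92%, at fold 0.5 for 96%, 92%, 96% and 96%, and at fold 0.25 for 98%, 100%, 96% and 98%. Genes simulated without a difference had intervals that excluded 1 in 71.3%, 35.9%, 18.9% and 3.35%, because the total moves with the changed genes, so an interval that excludes 1 is no call. Lists at folds 4 and 2 came out at percentile 100 and those at 0.5 and 0.25 at percentile 0 in all 4 classes.

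Alternatives changed doublet removal, the mitochondrial limit (10%), the minimum of UMIs (2000), the resolution (1.2), joint clustering, scaling, the weight of cells, the pseudocount (5 CPM), the minimum level of list members and cell calling. Others were added after the values were seen: removal of top doublet scores at the expected rate, another name for cluster 1 of the day 9 embryo, trophectoderm-like cells without cluster 3 of the day 12 embryo, cells of the day 9 embryo called at 1000 UMIs, and only list members above the rest of the library. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used.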

Results

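The data were single-cell RNA sequencing of pig conceptuses and of the lining of the uterus, at 9 and 12 days of pregnancy, the interval in which the pig conceptus grows from a sphere towards a filament. The 4 groups (embryo day 9, embryo day 12, endometrium day 9 and endometrium day 12) held 1 library each, so no difference between days had a replicate check and none was tested. Deposited totals were 109449139 UMIs (molecules counted once by their barcode) in the day 9 embryo, 66992264 in the day 12 embryo, 27250593 in the day 9 endometrium and 27589239 in the day 12 endometrium. After filtering, 7000, 6657, 7984 and 8962 cells remained, in that order, with medians of 11884, 9343.5, 2639 and 2233 UMIs per cell. All intervals are 95% and cover counting error only, not the variation between animals. Levels are CPM (counts scaled to a fixed total) of the summed counts of a class of cells in a library, and the level in the rest of the same library is given where free RNA or other classes bear on a value.

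The first question was which cell classes made up the embryo on each day. Trophectoderm-like cells, the outer layer that becomes the placenta, were 9.34% of the day 9 library (8.67 to 10.0%) and 48.7% of the day 12 library (47.5 to 49.95%), by exact binomial intervals. Hypoblast-like cells, the future yolk sac endoderm, were 47.3% (46.1 to 48.5%) on day 9 and 37.1% (35.9 to 38.2%) on day 12. Epiblast-like cells, the source of the fetus itself, were 0.3% (0.186 to 0.458%) and 1.32% (1.06 to 1.63%). Mesoderm-like cells were 3.79% on day 12 (3.34 to 4.27%), and 0 of 7000 cells on day 9 stood in a cluster of that name. By the exact interval this allows such clusters a share of up to 0.0527%, and it leaves open what the other clusters, named or unnamed, hold. Different clusters held each class in the libraries: clusters 2, 3 and 6 on day 9 and 2, 4 and 7 on day 12 for hypoblast-like cells, cluster 4 against clusters 1, 3 and 8 for trophectoderm-like cells, and cluster 8 against cluster 9 for epiblast-like cells. A cluster found in 1 library may stand for that library and not for a cell type. Unnamed clusters held 43.1% of the day 9 cells and 9.09% of the day 12 cells. The largest of them, day 9 cluster 1 with 2571 cells, had 11 of 14 detected hypoblast markers high, but its leading genes held more markers of another class than of hypoblast. Counting it as hypoblast-like moved the difference in the hypoblast-like share from -10.2 to -47.0 percentage points. With Scrublet doublets kept (7001 day 9 cells), 7.0% of day 9 cells were unnamed and that difference was -45.7 points. Under the alternatives it ran from -47.0 to -7.05 points. The hypoblast-like shares of 47.3% and 37.1% therefore depend on how the day 9 clusters fell and were named. The trophectoderm-like difference of 39.4 points came to 17.3 points when both libraries were clustered together. In that setting 28.0% of the day 12 cells were trophectoderm-like and 29.6% unnamed. Day 12 cluster 3, named trophectoderm-like, held 20.2% of the cells at a median of 3920 UMIs, with the mitochondrial genes ND5, ND4L and ND2 among its leading genes. The day 9 embryo was the only library deposited before cell calling, which also bears on these shares.

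**Figure D1:**
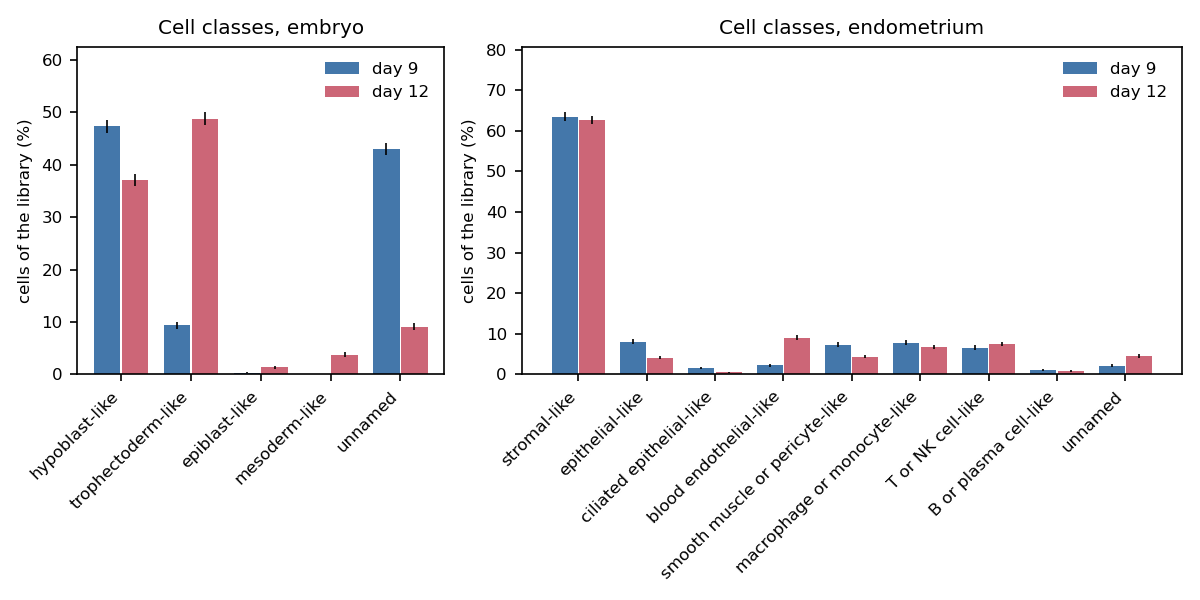
Share of the cells of each library (percent, vertical axis) in each class of the embryo (left) and endometrium (right) on day 9 and day 12, 1 library per bar, with exact 95% binomial intervals that cover counting error only. The trophectoderm-like bar stands at 9.34% on day 9 and 48.7% on day 12, and the blood endothelial-like bar at 2.22% and 9.07%.

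In hypoblast-like cells (3311 on day 9, 2467 on day 12), FETUB, RBP4, TF and HAMP, which encode secreted proteins, ranked among the 10 highest ratios, while the abundant apolipoprotein gene APOA1 was at 20059 and 20881 CPM. FETUB, which encodes fetuin B, stood at 1.23 CPM on day 9 and 481 CPM on day 12 (393-fold, 296 to 533). RBP4, the retinol carrier of blood plasma, was 194-fold higher (167 to 226), at 890.1 CPM on day 12. The iron carrier transferrin (TF) was at 0.128 and 80.3 CPM, and HAMP, which encodes the iron-regulating hormone hepcidin, at 2.6 and 176 CPM. The metallothionein gene MT1A was at 9.67 and 1539 CPM, and TNFAIP3, a brake on NF-kappa-B signalling, at 0.383 and 114 CPM. PLET1, CTBS, CTSL and IFNG also ranked among the 10 highest ratios, but on day 12 these 4 were lower in hypoblast-like cells than in the rest of the library: PLET1 was at 587 against 8805 CPM, CTBS at 165 against 2712 CPM, CTSL at 289.5 against 3742 CPM and IFNG at 50.9 against 543 CPM. PLET1 had 0 counts on day 9, so its ratio was at least 7670.3-fold against a floor of 3 counts. IFNG rested on 3 counts on day 9 (664-fold, 227 to 3226). FOLR1, a folate receptor gene, was 24.7-fold lower in the day 12 library (20.8 to 29.6), at 117 and 4.73 CPM. The scaffold gene AKAP12 was 12.1-fold lower (11.003 to 13.4), the ion cotransporter gene SLC12A2 8.5-fold lower (7.96 to 9.08), and the activin inhibitor follistatin (FST) 5.68-fold lower (5.51 to 5.86). EMP1, INSIG1, NIN, GPATCH4, MSMO1 and POLR1G completed the 10 lowest ratios, from 5.37-fold lower for INSIG1 to 4.64-fold lower for POLR1G. FOLR1, EMP1 and GPATCH4 stood slightly below the rest of the library on day 9, at 123, 949 and 117 CPM there. That rest was mostly unnamed clusters (38586929 UMIs, against 4438017 in trophectoderm-like cells). Among them was cluster 1, with 11 of 14 hypoblast markers high. The day 9 rest may therefore hold further hypoblast-like cells, which also limits the choice of list members above the rest in this class.

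Gene lists set those differences in context. All 17 measured genes of cholesterol synthesis and uptake had lower values in the day 12 hypoblast-like cells, SREBF2 by less than its counting error, with a median log2 ratio of -1.22, below all of 10000 random lists matched on expression. INSIG1, which senses sterols, was at 57.9 and 10.8 CPM, and the sterol oxidase gene MSMO1 at 117 and 23.4 CPM, while SREBF2 was at 55.4 CPM on both days. All 14 cell cycle genes of G2 and M were lower as well (median -0.70, percentile 0.28), with CENPF at 60.4 and 22.2 CPM and PLK1 at 99.5 and 43.5 CPM. Of 12 glycolysis genes, 8 were higher and 4 lower (median 0.40, percentile 99.5), and the median was 0.15 with no minimum level. Among cytokines and growth factors, 7 of 9 were higher, with HBEGF, a ligand of the EGF receptor, at 101 and 357 CPM. HBEGF was also among the leading genes of the unnamed day 9 cluster 1. Leaving that cluster out of the class may therefore carry a part of the HBEGF difference. Trophectoderm regulators were higher in 6 of 9 (median 1.19, percentile 99.96; 0.39 over the 4 members above the rest of the library), with HAND1 at 2.25 and 87.0 CPM against 1508 CPM in the rest of the day 12 library. Clusters 2, 4 and 7 of day 12 also had 3, 3 and 5 trophectoderm markers high, so RNA or cells of that class stay open as a part of the hypoblast-like differences. The genes that cell dissociation induces differed in the same libraries: 11 of 13 were higher on day 12 (median 1.48, percentile 100), with NR4A1 at 6.74 and 105 CPM. Over genes at 50 CPM or more on both days, the median log2 ratio in hypoblast-like cells was -0.16, the amount by which scaling on the median of ratios moves each value.

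**Figure D2:**
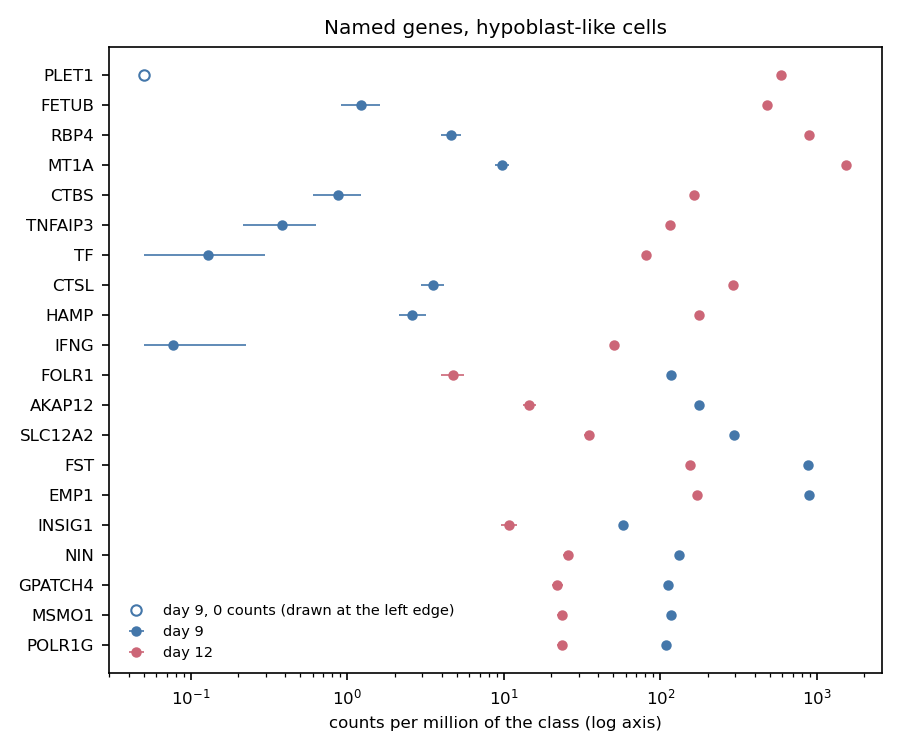
Levels of the 20 named genes in hypoblast-like cells (CPM of the class, log axis) on day 9 and day 12, 1 library per point, with exact 95% Poisson intervals. An open circle at the left edge stands for 0 counts, as for PLET1 on day 9, which was at 587 CPM on day 12, and FOLR1 stands at 117 CPM on day 9 and 4.73 CPM on day 12.

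In trophectoderm-like cells (654 on day 9, 3245 on day 12), IL1B2, the interleukin 1 beta gene that pig conceptuses secrete, was 252-fold lower in the day 12 library (226 to 282), at 2962 and 11.7 CPM. IFNG, the gene of interferon gamma, which the pig trophoblast also secretes, was 141-fold higher (92.4 to 228), at 4.73 and 668 CPM. PLET1 was at 1.35 CPM from 6 counts on day 9 and 10884 CPM on day 12, and the chitobiase gene CTBS at 1.8 and 3361 CPM. ENTPD8, with 3 counts on day 9, was 435-fold higher (149 to 2110.5), the selenium carrier SELENOP 182-fold higher (102 to 365), and PROM2, with 0 counts on day 9, at least 257-fold higher. UPP1, a uridine phosphorylase gene, was 337-fold lower (241 to 489), RBP2 524-fold lower (298 to 1017), the zinc transporter gene SLC30A2 123-fold lower (75.5 to 213) and GM2A 41.5-fold lower (38.3 to 45.03). The classes also differed in quality, with medians of 5689 UMIs and 0.548% mitochondrial UMIs per cell on day 9 against 8226 UMIs and 3.63% on day 12. IL1B2 was at 35.4 CPM in the rest of the day 9 library and IFNG at 50.5 CPM in the rest of the day 12 library.

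Of 13 measured steroid synthesis genes, 8 were lower and 5 higher in the day 12 trophectoderm-like cells (median -1.003, percentile 0.04). HSD17B1, which makes oestradiol from oestrone, was 14.9-fold lower (14.4 to 15.3), at 3224 and 217 CPM, and FDXR was at 173 and 53.3 CPM, while CYP19A1, the aromatase gene, was at 9.01 and 52.5 CPM. Of 9 cytokines and growth factors, 8 were higher (median 2.14, percentile 99.98), IL1B2 being the exception; the median was 1.04 with no minimum level. The prostaglandin list had a median of -0.18 with members on both sides: PTGS2, which starts prostaglandin synthesis, was at 6.99 and 325 CPM, and PTGES at 612 and 77.3 CPM. All 6 pluripotency regulators were higher (median 2.69, percentile 99.98), with DPPA5 at 74.6 and 1344 CPM, but the median was 0.66 with no minimum level. Among 14 trophectoderm regulators 11 were higher (median 0.90, percentile 98.4), with HAND1 at 204 and 1730.1 CPM and ASCL2 at 78.4 and 1.76 CPM. Adhesion genes had a median of 1.46 (7 of 10 higher), which turned to -0.46 when both libraries were clustered together and to -0.33 with day 9 cells called at 1000 UMIs. The keratin gene KRT18 stood at 22334.5 CPM on day 9 and 2959 CPM on day 12. Genes induced by dissociation were again higher on day 12 (11 of 13, median 2.25), and the median over genes at 50 CPM or more on both days stood at -0.29. The steroid median was -0.42 with no minimum level for list members.

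In the endometrium the question was the same, for the cells that face and underlie the conceptus. Stromal-like cells were 63.4% (62.4 to 64.5%) of the day 9 library and 62.6% (61.6 to 63.6%) of the day 12 library, a difference of -0.88 percentage points whose interval (-2.34 to 0.59) held 0. Blood endothelial-like cells were 2.22% (1.91 to 2.56%) and 9.07% (8.48 to 9.69%). Epithelial-like cells were 8.0% (7.42 to 8.62%) and 4.07% (3.67 to 4.503%), and ciliated epithelial-like cells 1.53% (1.27 to 1.82%) and 0.48% (0.347 to 0.646%). Smooth muscle or pericyte-like cells were 7.34% and 4.37%, macrophage or monocyte-like cells 7.75% and 6.69%, T or NK cell-like cells 6.59% and 7.42%, and B or plasma cell-like cells 0.964% and 0.859%. Unnamed clusters held 2.17% and 4.46%. Among them, day 9 cluster 11 (157 cells) had CD3E and CD8A among its leading genes, with 12 of 14 stromal markers high. Day 12 cluster 8 (352 cells) had KLRB1 and KLRK1 among its leading genes, with 8 of 14 stromal markers high. The T or NK cell-like shares may therefore leave out such cells on both days. Stromal-like cells lay in clusters 1, 2 and 5 on day 9 and 1, 2, 6, 7 and 11 on day 12, epithelial-like cells in 6 and 8 against 9, 14 and 17, and blood endothelial-like cells in cluster 10 against cluster 3. With at least 2000 UMIs per cell, the macrophage or monocyte-like difference of -1.06 points turned to 1.45 points. The same setting moved the stromal-like difference to -8.16 points and the T or NK cell-like difference from 0.83 to 6.06 points.

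In stromal-like cells (5065 and 5607), IDO1, which degrades tryptophan, had the highest ratio and was at 0.541 and 115 CPM (213-fold, 108 to 494). The guanylate binding protein gene GBP2 was at 6.62 and 78.1 CPM, but at 91.6 CPM in the rest of the day 12 library, and the complement gene C2 at 2.03 and 50.5 CPM. FMO1 was 23.9-fold higher (22.1 to 25.8), SERPINA3-2 68.8-fold (48.6 to 101), KIF9 17.8-fold (16.2 to 19.5), GHSR 15.4-fold (13.7 to 17.4) and the retinal dehydrogenase gene ALDH1A1 14.3-fold (13.1 to 15.5). The insulin-like growth factor binding protein gene IGFBP2 was at 39.7 and 602 CPM, and MGP at 38.0 and 386 CPM. On day 12, IDO1 was among the leading genes of cluster 7 (475 cells) and SERPINA3-2 among those of cluster 6 (571 cells). IGFBP2 and ALDH1A1 were among those of cluster 2 (1802 cells), and MGP among those of cluster 11 (182 cells). Single stromal-like clusters may therefore carry a part of these values. PENK, the proenkephalin gene, was 87.3-fold lower on day 12 (64.2 to 122), at 268 and 3.08 CPM, and ST6GAL2 90.1-fold lower (53.5 to 165). The matrix genes PRELP and COL15A1 were 24.1-fold (20.6 to 28.5) and 14.5-fold (13.2 to 15.996) lower. OPCML, COX4I2, CRABP2, GALNT16, SOX18 and ISYNA1 were 30.4-fold to 10.0-fold lower.

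Of 26 measured interferon response genes, 20 were higher in the day 12 stromal-like cells (median 0.99, percentile 100). GBP1 was at 13.6 and 704 CPM, while MX1 was at 286 and 181 CPM and MX2 at 96.1 and 74.0 CPM. Over the 12 members that were higher in stromal-like cells than in the rest of a library, the median was 0.45. Chemokines and inflammatory cytokines were higher in 14 of 15 (median 1.10, percentile 100), with CXCL10 at 195 and 1619 CPM and IL6 at 9.87 and 86.9 CPM, and the median was 0.61 with no minimum level; CXCL10 was at 3204 CPM in the rest of the day 12 library. Extracellular matrix genes had a median of 0.38 (13 of 21 higher, percentile 99.3), with DCN at 6909 and 16519 CPM and BGN at 157 and 82.1 CPM. DKK1, a WNT inhibitor, was 9.93-fold higher (9.55 to 10.3). The oestrogen and progesterone receptor system was split, 7 higher and 7 lower (median -0.04). Genes induced by dissociation were higher in 13 of 14 (median 0.70).

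**Figure D3:**
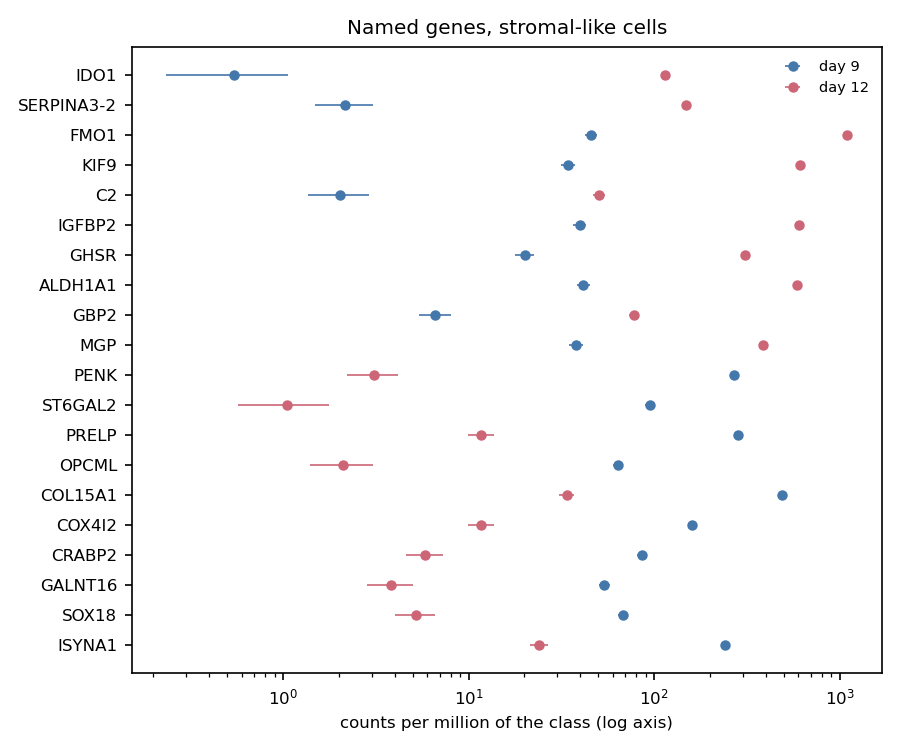
Levels of the 20 named genes in stromal-like cells (CPM of the class, log axis) on day 9 and day 12, 1 library per point, with exact 95% Poisson intervals. IDO1 stands at 0.541 and 115 CPM and PENK at 268 and 3.08 CPM.

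In epithelial-like cells (639 and 365), RBP4 was at 217 and 10121 CPM (46.7-fold, 43.4 to 50.2), against 106 CPM in the rest of the day 12 library. STC1, the stanniocalcin gene, was at 23.3 and 695 CPM, and NMB, which encodes the peptide neuromedin B, at 58.6 and 3044 CPM. S100A12 was at 0.548 CPM from 2 counts and 1645 CPM (3004-fold, 831 to 24816). NMU rested on 1 count on day 9 (1642-fold, 294 to 64936) and the uteroferrin-associated gene UABP-2 on 3 counts (764-fold, 260.5 to 3711). CD24 was at 5.48 and 822 CPM. UABP-2 was among the leading genes of day 12 cluster 14 (58 cells) and CD24 among those of cluster 17 (19 cells), so small clusters may carry a part of these values. HDC, which makes histamine, was at 125 CPM on day 9 and had 0 counts on day 12, at least 60.2-fold lower. RAB26 was 137-fold lower (66.3 to 341), the water channel gene AQP3 95.7-fold lower (32.6 to 465), DISP3 53.0-fold lower (18.0 to 258) and FXYD4 39.8-fold lower (24.8 to 68.4). RAB26 and FXYD4 were among the leading genes of day 9 cluster 6 (369 cells), and AQP3 among those of cluster 8 (270 cells). A different mix of epithelial cells in the libraries therefore stays open as a part of these lower values.

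Of 19 secreted uterine protein genes, 16 were higher in the day 12 epithelial-like cells (median 1.23, percentile 100), and the median was 2.19 over the 11 members above the rest of the library, a choice of members that the difference itself affects. Genes induced by dissociation were higher in 14 of 14 of the same cells (median 0.61, percentile 98.9). Of 22 genes listed from earlier work on days 12 and 13, 15 were higher (median 1.496, percentile 100). Tight and adherens junction genes had a median of 0.13 with 11 of 16 higher: CLDN4 was at 612 and 2813 CPM, and CLDN10 at 101 and 10.4 CPM. The transporter list was split, 9 higher and 9 lower, with the monocarboxylate transporter gene SLC16A1 at 5.75 and 195 CPM. The interferon response median of 0.35 (16 of 27 higher) turned to -0.97 over the 5 members that lay above the rest of the library, among them OASL at 29.9 and 2.77 CPM. FOXA2, a regulator of uterine glands, was at 43.0 and 3.46 CPM.

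Blood endothelial-like cells (177 and 813) had higher cell cycle genes in the day 12 library. All 12 measured genes of G2 and M were higher (median 2.37, percentile 100; 1.44 with 5 CPM added), with NUSAP1 at 8.62 and 67.0 CPM and UBE2C, from 3 counts, at 2.35 and 57.9 CPM. IL33, an alarm cytokine gene, was 10.2-fold higher (7.06 to 15.3), against 4.04 CPM in the rest of the library, CXCL10 was at 231 and 2544 CPM and WARS1 at 21.2 and 182 CPM. DKK1 was at 201 CPM on day 12, below the 1284 CPM of the rest. PCP4 was 249-fold lower (96.0 to 918), CYP2E1 164-fold (44.2 to 1374), PRELP (below the rest of the library) 23.8-fold (12.2 to 51.9), RGS4 13.1-fold (8.71 to 20.3) and HIGD1B 12.4-fold (9.29 to 16.7). PCP4 and HIGD1B stood higher in the day 9 smooth muscle or pericyte-like cells, at 716 and 647 CPM against 226 and 174 CPM, so RNA or cells of that class stay open as a part of these 2 differences. Interferon response genes were higher in 18 of 28 (median 0.65), vessel growth genes in 11 of 18 (median 0.24), and nutrient and ion transporters lower in 11 of 15 (median -0.89, percentile 0), with SLC7A5 at 88.5 and 10.7 CPM. In smooth muscle or pericyte-like cells (586 and 392; clusters 7 and 9 against 10 and 12), all 9 cell cycle genes were higher (median 2.35). Day 9 cluster 7 (333 cells) had 7 of 14 stromal markers high against 3 of 12 of its own class, and day 12 cluster 10 (212 cells) 4 of 14 against 4 of 12, so a part of this class may be stromal. Of the genes named there, CCL11 was at 2.28 and 53.8 CPM, and CXCL10 at 288 and 3099 CPM against 2344 CPM in the rest of the library; KIF9, GHSR and FMO1 lay below the rest. MT3 was at least 20.3-fold lower, CCL28 was at 60.7 CPM on day 9 with 1 count on day 12, and DPT, KRT8 and PENK were 12.5-fold (6.84 to 25.6), 12.3-fold (6.29 to 27.4) and 11.8-fold (6.42 to 24.0) lower; all of these but DPT lay below the rest on day 9. CCL11 turned to a log2 ratio of -0.15 at the finer clustering resolution.

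In macrophage or monocyte-like cells (619 and 600; cluster 3 against 5), CXCL10, a chemokine gene that interferons induce, was 32.4-fold higher (29.9 to 35.3), at 324 and 10513 CPM, and BATF2 22.7-fold higher (13.3 to 41.9). CD209, a lectin of resident macrophages, was at 639 CPM and 1.41 CPM, LYVE1 at 131 and 1.41 CPM, and the protease gene CTSL at 353 and 9.38 CPM. CALML4 was 20.8-fold lower (11.04 to 44.1), and CCL28, below the rest of the library on day 9, at least 42.2-fold lower. FMO1, KIF9 and HPS5 were higher, but below the rest of the library on day 12. Interferon response genes were higher in 21 of 28 (median 1.08, percentile 100), cell cycle genes in 13 of 13 (median 1.63) and vessel growth genes lower in 7 of 10 (median -0.91, percentile 0.02; -0.13 with no minimum level), with PDGFB at 80.7 and 12.7 CPM. IL10 was at 204 and 18.8 CPM. In T or NK cell-like cells (526 and 665; clusters 4 and 14 against 4), interferon response genes were higher in 16 of 24 (median 0.47), with GBP1 at 223 and 1009 CPM, and cell cycle genes in 13 of 14 (median 1.18), which turned to -1.0002 with at least 2000 UMIs per cell. In the same cells 9 of 14 genes induced by dissociation were higher (median 0.40, percentile 98.97). All 10 genes named in T or NK cell-like cells (FMO1, CXCL10, SOD3, DKK1, SERPING1, CCL28, KRT8, ANXA4, MT1A and MT3) lay below the rest of the library on the day they were higher. Of the 10 named in B or plasma cell-like cells (77 and 77), 9 did so (FMO1, DKK1, CXCL10, RBP4, SLA-DMA, C4BPA, MT1A, KRT8 and SST); the other, TLCD4, was 61.4-fold lower from 1 count on day 12 (10.6 to 2463). The median there over genes at 50 CPM or more on both days stood at -0.15.

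**Figure D4:**
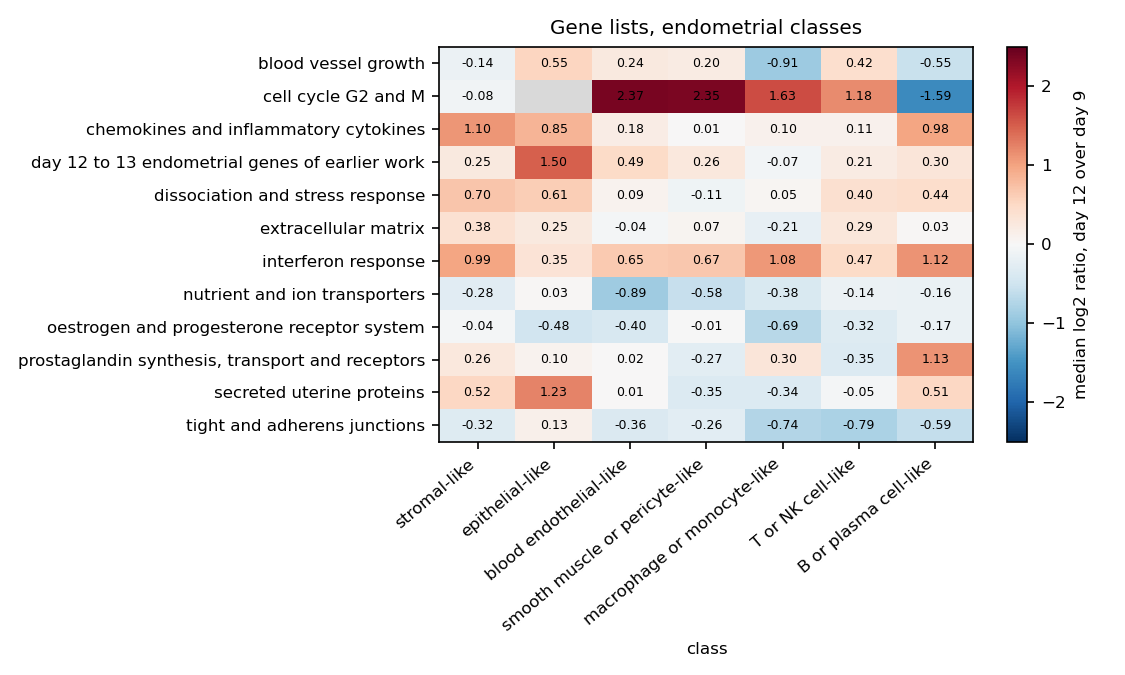
Median log2 ratio of day 12 over day 9 (colour and printed value) for each gene list (vertical axis) in each endometrial class (horizontal axis), 1 library per day; grey marks a list with under 3 measured genes. Cell cycle genes stand at 2.37 in blood endothelial-like and 1.63 in macrophage or monocyte-like cells, and secreted uterine proteins at 1.23 in epithelial-like cells.

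The series title names exchange between embryo and uterus, so levels of ligands and receptors were set side by side. Of 32 pairs of an embryo ligand and an endometrial receptor with both symbols, 7 had both at 20 CPM or more in some class of at least 50 cells on day 9 and 13 on day 12, 6 of them on both days. The classes of that size differed between days: mesoderm-like and epiblast-like cells reached it only on day 12 and ciliated epithelial-like cells only on day 9. Over the classes that reached it on both days the counts were 7 and 11, without both BMP4 pairs. IL1B2 with its receptor gene IL1R1 met that level on day 9 only: the ligand stood at 2962 CPM in trophectoderm-like cells, and the receptor at 84.4 CPM in epithelial-like cells. IFNG with IFNGR1 and IFNGR2 met it on day 12 only, with IFNG at 668 CPM, IFNGR1 at 98.8 CPM in T or NK cell-like cells and IFNGR2 at 77.4 CPM in macrophage or monocyte-like cells; the receptor genes stood at 173 and 88.6 CPM on day 9. BMP4 was at 239 CPM in mesoderm-like cells on day 12, a class with no day 9 value, TGFB1 at 36.3 CPM in trophectoderm-like cells, and WNT5A at 37.6 CPM in hypoblast-like cells. HBEGF and EREG met it with EGFR on both days, as EGFR stood at 103 CPM on day 9 and 40.2 CPM on day 12 in epithelial-like cells; ciliated epithelial-like cells had 162 CPM on day 9 and, with 43 cells, were left out on day 12. In the other direction, 5 of 28 pairs met the level on day 9 and 9 on day 12, also over the classes that reached 50 cells on both days. FGF9 was at 48.5 CPM in day 12 epithelial-like cells, with FGFR3 at 118 CPM in hypoblast-like cells, and WNT5A at 137 CPM in stromal-like cells, with FZD5 at 150 CPM in trophectoderm-like cells and 8.01 CPM at most on day 9. SPP1, or osteopontin, was at 28.2 and 213 CPM in blood endothelial-like cells, and its receptor gene ITGAV at 81.0 and 73.3 CPM in hypoblast-like cells. RNA levels in separate libraries do not show that a ligand reached its receptor.

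**Figure D5:**
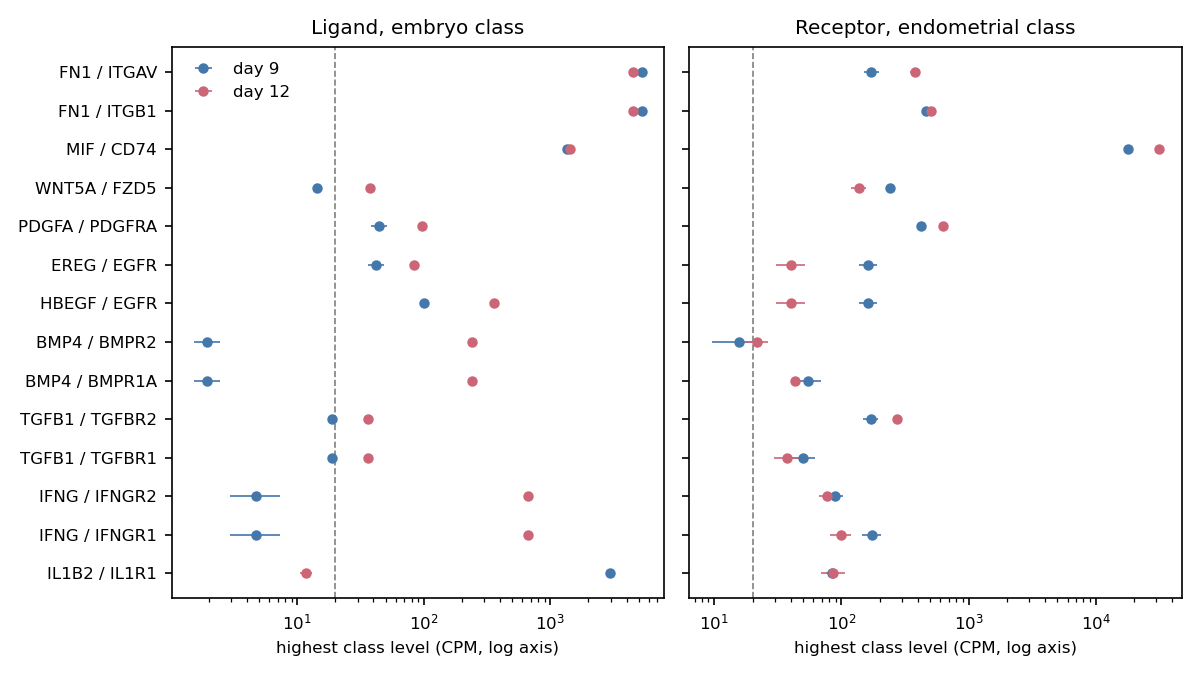
Highest class level (CPM, log axis) of embryo ligands (left) and of their endometrial receptors (right) on day 9 and day 12 for the 14 pairs with both at 20 CPM or more (dashed line) on a day, 1 library per point, with exact 95% Poisson intervals. IFNG moves from 4.73 to 668 CPM and IL1B2 from 2962 to 11.7 CPM.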

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

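All 5 tests in this part were chosen after the results were seen, and for the interferon cluster the deciding value was switched from the median over 5 stromal genes (0) to the highest of them. The test of stromal RNA in epithelial-like cells replaced a median over genes above the rest of the library (2.19), because the difference itself affects which genes those are. The test of cell calling replaced a minimum of 2000 UMIs (day 9 share 10.5%), which left cells of 1000 to 2000 UMIs unexamined. CTSL stood out because it differed in opposite directions between tissues: its log2 ratio was 6.01 in hypoblast-like cells and -5.09 in macrophage or monocyte-like cells. MT1A did so too, at 7.17 in hypoblast-like cells against -2.94 in T or NK cell-like and -2.71 in B or plasma cell-like cells. These differences between tissues were not tested. In data outside the comparisons, KRT8 stood at 8128 CPM in the barcodes with 200 or more but under 500 UMIs of the day 9 embryo. The unnamed cluster 10 of the day 12 embryo (21 cells) had NMB at 5369.5 CPM and SPINK9 at 2711 CPM. NMB lay between 5.33 and 37.8 CPM in the other clusters of that library, but at 3044 CPM in day 12 epithelial-like cells of the endometrium. SPINK9 was among the leading genes of day 12 endometrial cluster 17, named epithelial-like. Maternal cells therefore stay open for cluster 10 of the embryo, untested.

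The trophectoderm-like share was 9.34% on day 9 and 48.7% on day 12. Whether cell calling is the whole reason was examined first. With cells called at 1000 UMIs, the minimum of the day 12 library, the day 9 share came to 11.6% (10.9 to 12.2%). Counting in as many unnamed cells as the highest of 8 markers allows gave 21.4% (20.6 to 22.3%), under the bound of 24.4%, 0.5 of the day 12 share. The outcome turns with other day 12 shares, which were 30.4% with at least 2000 UMIs in both libraries, 29.4% with at most 10% mitochondrial UMIs, 28.0% with joint clustering, 27.4% without top doublet scores and 39.6% at resolution 1.2: 21.4% exceeds 0.5 of each of these. The 21.4% stays below each of them. Those day 12 shares leave out unnamed cells (24.0%, 26.4%, 29.6%, 29.8% and 18.1% of day 12 cells, in that order), while the 21.4% counts some in. If unnamed day 9 cells carry the marker levels of the named trophectoderm-like cluster, calling alone would not make the shares equal. Calling stays open for a part of the difference. Loss of cells in dissociation stays open and could account for part of it, since over 8 markers trophectoderm RNA took a median of 11.09% of the RNA in those barcodes with under 500 UMIs but 5.38% of the UMIs of called cells, a median ratio of 2.06 (lowest and highest marker 1.34 and 6.14). Growth of the trophectoderm between the days also stays open, untested.

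Cluster 8 of the day 12 embryo (94 trophectoderm-like cells) had ISG15 at 1200.1 CPM, MX1 at 193 CPM and OAS2 at 47.5 CPM, against 27.9, 2.85 and 3.48 CPM in cluster 1. Only 7 of 29 interferon response genes stood at 20 CPM or more in cluster 8 and at least 2 times as high as in cluster 1. Its 10 leading genes also held IFI6, BST2, ISG12(A), IFI44L, USP18 and ADAR, which are not on that list. IFIT1 was at 1.98 CPM, RSAD2 at 0.99 CPM, and IFIT2, GBP1, GBP2, PSMB8 and CXCL10 at 0 CPM. Maternal stromal RNA or cells at the share these genes need (median 10.2%) would bring stromal genes. The highest of 5 came to 0.0019 of the level needed, with COL1A1 at 1.98 CPM and DCN at 0 CPM. Other maternal classes would bring less of these genes, so for them the B2M level is the value that bears on the question. B2M at 135 CPM (upper limit 159 CPM) allows at most 2.27% of maternal RNA even if all of it is maternal, given the lowest endometrial class level of 7002 CPM. An interferon response of some trophectoderm cells, in a part of these genes, is a hypothesis from the same data.

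Secreted uterine protein genes were higher in the day 12 epithelial-like cells (median 1.23). A different mix of the same clusters does not account for all of this. The main day 12 cluster exceeded the higher of both day 9 clusters by a median of 0.47 (0.34 to 1.01), in 15 of 19 genes. That median is below 1.23, so mix stays open for a part, as for ACP5 (log2 ratio 0.052) and CLU (0.093). The gene at the median, LTF, was near the minimum level, at 5.78 CPM in the main day 12 cluster and 3.89 CPM in day 9 cluster 6. Free RNA of stromal cells alone does not account for the median. With stromal RNA taken off at 15.6% of its level, the highest share that 5 stromal genes allow, 12 of 19 genes stayed higher. The median over all 19 was then 1.003 (0.81 to 1.18). Mix and stromal RNA were examined one at a time, so both together stay open. IGF1, IGFBP5 and IL6 came to 0 CPM in that step and CSF1 turned to a log2 ratio of -1.09, so stromal RNA stays open for these 4. A response to the stage of pregnancy is a hypothesis, and an animal's own level stays open with 1 library per day.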

How the results depend on the processing

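Of 83 differences in shares under alternatives, 78 kept their sign; of 1198 list medians 1110 did, and of 4617 gene ratios 4525. The causes of the values given here were not tested. Depth limits the small classes: B or plasma cell-like cells held 819350 and 774159 UMIs, against 14797392 and 13331142 in stromal-like cells. Shares are in percentage points, genes and lists in log2.

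With Scrublet doublets kept, shares were hypoblast-like -45.7, epiblast-like 1.86 and mesoderm-like 3.09, and DNMT3B in hypoblast-like cells 0.0058. At most 10% mitochondrial UMIs gave hypoblast-like -33.1, trophectoderm-like 19.96, epiblast-like 1.56, stromal-like 1.01, epithelial-like -3.07 and smooth muscle or pericyte-like -5.57; DNMT3B in hypoblast-like cells was 0.020, CCL2 in T or NK cell-like cells 0.15, and in smooth muscle or pericyte-like cells the secreted list was 0.011, PTGS2 -0.63, COL4A2 -0.25 and CXCL12 -2.74. At least 2000 UMIs gave hypoblast-like -7.05, trophectoderm-like 21.1, epiblast-like 1.39, stromal-like -8.16, blood endothelial-like 8.05, smooth muscle or pericyte-like -0.68, macrophage or monocyte-like 1.45, T or NK cell-like 6.06 and B or plasma cell-like 0.814, an interferon median of 0.83 in stromal-like cells and DUSP1 at 0.34 in B or plasma cell-like cells. In T or NK cell-like cells it left 7 lists apart, with junctions at 0.45, cell cycle -1.0002, CCL2 2.68, ANXA4 0.022, MX1 0.36, MX2 1.09, FKBP4 -0.77, ESR1 1.17, PTCH1 2.43, COL6A3 1.40, BGN 0.82, CXCL2 1.34, TOP2A -0.53, UBE2C -0.72 and FOSB 1.93.

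Leiden resolution 1.2 gave hypoblast-like -45.7, trophectoderm-like 30.6, epiblast-like 1.82, mesoderm-like 2.99 and smooth muscle or pericyte-like -4.29; in the last class the secreted list was 0.028, PTGS2 -0.40, COL4A2 -0.13, CXCL12 -3.00 and CCL11 -0.15. Joint clustering gave hypoblast-like -45.7, trophectoderm-like 17.3 and mesoderm-like 4.52, with steroid synthesis at -0.75 and adhesion at -0.46 in trophectoderm-like cells and CCL2 at 0.26 in T or NK cell-like cells. Calling at 2000 UMIs gave hypoblast-like -41.5, and calling at 1000 UMIs hypoblast-like -22.3 and trophectoderm-like 37.2, with steroid synthesis at -0.80, adhesion at -0.33 and KLF5 at -0.012 in trophectoderm-like cells. Removal of top doublet scores gave hypoblast-like -46.9, trophectoderm-like 17.6 and blood endothelial-like 6.13, CXCL2 -0.30 in epithelial-like and CCL2 0.085 in T or NK cell-like cells. Cluster 1 counted as hypoblast-like gave -47.0.

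Median of ratios scaling gave cholesterol -1.06 and DNMT3B 0.038 in hypoblast-like, steroid synthesis -0.72 in trophectoderm-like and interferon 1.07 in stromal-like cells. The mean over cells gave cholesterol -1.16, ATF3 -0.023 in epithelial-like cells and cell cycle 0.042 in B or plasma cell-like cells. A pseudocount of 5 CPM gave cholesterol -1.16 and stromal-like interferon 0.72. With no minimum level, steroid synthesis was -0.42 and stromal-like interferon 0.70. Members above the rest gave cholesterol -1.37, interferon 0.45 in stromal-like, -0.97 in epithelial-like and -0.042 in smooth muscle or pericyte-like cells, vessel growth -0.86 and secreted proteins 2.19 in epithelial-like cells.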

Other observations

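The 2 groups of interferon genes compared here were formed after the interferon response values were seen, and no test was run on them. Genes that interferon gamma induces had medians from 1.02 to 2.15 over 7 endometrial classes, which share 2 libraries and their free RNA. In macrophage or monocyte-like cells 9 of 11 of them lay above the rest of the library (median 2.07 over these), in blood endothelial-like cells 10 of 11 (median 1.13), in T or NK cell-like cells 6 of 9 (median 0.66), in smooth muscle or pericyte-like cells 6 of 11 (4 of them higher on day 12, median 0.96), in stromal-like cells 3 of 9 (median 1.22), and in epithelial-like and B or plasma cell-like cells 0 of 9, so free RNA stays open there. Genes typical of type I interferon had medians from -0.79 to 0.19, with 1 of 7 above 0; over members above the rest they were -0.41 in macrophage or monocyte-like, -0.34 in blood endothelial-like, -0.04 in stromal-like, -0.042 in smooth muscle or pericyte-like and -1.999 in epithelial-like cells (0 of 4 higher). IFNG was at 668 CPM in day 12 trophectoderm-like cells. IFN-DELTA-1, a type I interferon gene, was at 19.5 CPM in the same cells (553 counts), with 0 counts on day 9. Which interferon the endometrial values follow was not tested.

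Cell cycle genes of G2 and M were lower on day 12 in hypoblast-like cells (14 of 14). In trophectoderm-like cells 11 of 14 were lower, at percentile 2.62 of random lists, within the range from 2.5 to 97.5, and the median of -0.51 ran from -0.81 to -0.23 under the alternatives. They were higher in blood endothelial-like (12 of 12), smooth muscle or pericyte-like (9 of 9) and macrophage or monocyte-like cells (13 of 13). They were also higher in T or NK cell-like cells (13 of 14), where the median turned to -1.0002 with at least 2000 UMIs, but in 1 of 3 in stromal-like and 1 of 3 in B or plasma cell-like cells. Cluster 10 of the day 12 embryo had B2M at 7320 CPM and ISG15 at 4261 CPM. B2M stood at 7002 CPM or more in each endometrial class of day 12, so maternal cells stay open for that cluster. Unnamed cluster 15 held 16 cells in the day 9 endometrium, and the unnamed cluster 15 of the day 12 endometrium held 48.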
